A study of Homo sapiens with 12 samples.

How the data were processed

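Gene expression was measured on Illumina BeadChip arrays in 12 RNA samples of L-540, an established human Hodgkin lymphoma cell line kept in culture. Per the labels, cells were left untreated or were exposed for 24 h to 10 µM perifosine, to 5 µM sorafenib, or to both drugs at these doses, with 3 arrays per group that carry the letters A, B and C. Total RNA was amplified to biotinylated cRNA, per the labels' protocols. The labels do not say whether the 3 letters of a group stand for separate cultures, so the p-values measure only the spread between these arrays, which may be partly technical. The series title also names treatment in animals, and such samples were not analysed here.

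The deposited table of unnormalized values holds a mean bead intensity per probe and array on a linear scale and a detection p-value against the negative-control beads of the same array, per the file headers. BeadStudio is named in the submitters' processing notes, with no version. The deposited intensities have no value near 0 (the lowest is 230.89) and array medians from 404.3 to 648.7, so they were taken as neither background-subtracted nor scaled. A second deposited table of the authors holds normalized intensities of the same arrays on a linear scale. Its columns have nearly the same median (492.3 to 492.9) and rank the probes as the unnormalized columns do, and it served as an alternative. How the authors normalized it is not given in the sources used here.

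The array holds 48803 probes. The platform annotation gave 28098 of them 1 gene symbol and 13 several, and 20692 are unnamed here. No symbol had to be updated through its Entrez identifier. Background was corrected and values were normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp with the negative-control moments inferred from the detection p-values, offset 16, then quantile normalization and log2). Probes with a detection p under 0.01 on at least 3 of the 12 arrays were kept, which left 11904 probes, 10117 of them with 1 gene. Each gene was represented by its probe with the highest mean over the 12 arrays, which gave 8092 genes. Probes with several genes or without a name entered no gene-level test.

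The arrays detected between 9291 and 11657 probes. The number of arrays, 3 per group, limits the precision of every value. Combination array B had the highest median intensity (648.7), the fewest detected probes and the lowest limma array weight (0.291, against 0.664 to 1.69 on the other 11 arrays). Correlations within groups ran from 0.956 to 0.984.

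All 12 arrays entered 1 linear model with a mean per group (lmFit and eBayes), so that the 4 groups share an estimate of the spread. The 7 comparisons were each treatment against control, the combination against each drug, perifosine against sorafenib, and the interaction (the change with the combination minus the sum of the changes with the drugs alone, on the log2 scale). P-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05, and a second count required a change of at least 2-fold. Errors given as SE are those of the moderated limma fit, and those given as SD are between the 3 arrays of a group. A probe with a detection p under 0.01 on none or on 1 of the 3 arrays of a group has only a bound there, and its fold is then given as "at least", from the brighter group's mean against the higher of the dim probe's own value and the lowest value among detected probes.

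A total of 28 gene lists with 500 entries was fixed before the data were examined, and 26 of them had measured members. The results of 1 of the lists are not reported here. The lists cover pathways that fit the drugs and the cell type, and markers of B cells, T and NK cells, monocytes and macrophages, fibroblasts, epithelium and endothelium. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data and with fry. The genes named were set by a rule fixed at the same time. For each comparison with control it takes the 8 rising and 8 falling genes with the largest log2 change among those past the threshold whose arrays do not overlap with the control arrays, TRIB3 and the measured drug target kinases, and up to 4 members past the threshold of each list that passes. For the other comparisons it takes 5 rising and 5 falling genes and the list members. Genes outside the rule are said to be chosen after their values were seen. For 3 arrays against 3, non-overlap arises by chance in 10% of unchanged genes.

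The labels' letters are shared between the groups, so their pairing was checked from the residuals of the group means. Arrays with the same letter were correlated in perifosine and control (0.35, 0.32 and 0.27 for A, B and C), in sorafenib and control (0.28, 0.33 and 0.19) and in perifosine and sorafenib (0.38, 0.29 and 0.23), all above the limit of 0.1 set for a pairing. For the combination only array A met this limit against each other group. Combination array B correlated best with the arrays of letter C (0.18) and combination array C with those of letter B (0.23), so an exchange of these letters in this group stays open, and block values of comparisons with the combination use the letters as labelled. For the comparisons that met it, the value with the letter as a replicate block is given beside the main value where it moves a count by over 1.5 times or changes a call.

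The functions were tested on simulated data. Log2 values were drawn for the 8092 genes with their measured means and the moderated spreads of the limma fit to the data. In each of 20 runs 200 genes were changed. The simulated arrays had no pairing by letter, and none was given a wider spread, as combination array B has. For perifosine against control, 64.3% of 2-fold changes, 98.1% of 4-fold changes and 0.025% of 1.41-fold changes were recovered, and 5.2% of the calls in the 2-fold runs were false. For the interaction, 3.22% of 2-fold and 89.4% of 4-fold changes were recovered. Camera recovered a shift of 0.5 log2 units of the cholesterol list in perifosine arrays in 50 of 50 runs. The genes were drawn independently of each other, so these runs do not test camera under correlation between genes.

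The alternatives covered the background correction, the scaling, the authors' normalized table, the filter on dim probes, the rule from probes to genes, the replicate block, the arrays in the fit, the variance model, array weights and leaving out each array in turn. A block for the BeadChip slide was not run, since the tables used here name no slide.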

Results

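Gene expression was profiled in L-540, a cell line established from Hodgkin lymphoma, after 24 h with perifosine, with sorafenib, with both drugs, or without a drug. Perifosine is an alkylphospholipid that interferes with AKT signalling, and sorafenib inhibits several kinases. Each of the 4 groups had 3 arrays, and 8092 genes were tested. The arrays detected 10739 ± 561.7 probes in control cells, 10800 ± 602.4 with perifosine, 10997 ± 677.6 with sorafenib and 10594 ± 1150 with the combination (mean ± SD, n = 3). The first principal component held 28.3% of the variance and separated the 6 arrays with sorafenib, all with scores above 0, from the 6 without it, all below 0. The second held 18.7%, and its most extreme score, -34.33, was that of combination array B.

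Of the cell type markers fixed beforehand, few were above background. BLK was the measured member of the B cell list. CD2, CD247 and NKG7 were measured among 10 markers of T and NK cells and were detected on all 3 control arrays, with log2 intensities of 10.42, 12.92 and 15.30. CD68 and S100A8 of the macrophage list and COL3A1 and PDGFRA of the fibroblast list were near background, and none of the epithelial or endothelial markers was above it. The 4 marker lists with measured members did not pass in any comparison with control (camera, adjusted p from 0.372 to 0.971).

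**Figure D1:**
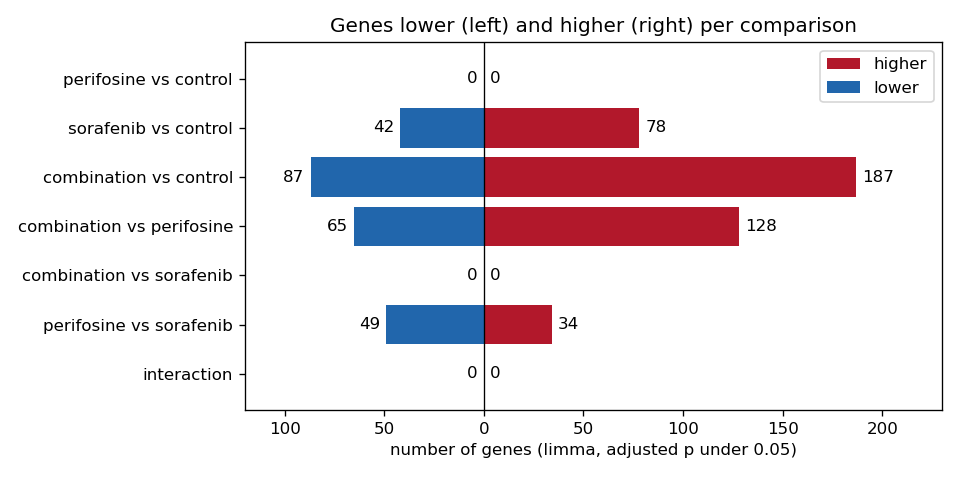
Number of genes past an adjusted p of 0.05 in limma for each of the 7 comparisons, with genes that were lower drawn to the left and genes that were higher drawn to the right. In this main fit the combination against control had the largest count, with 187 genes higher and 87 lower, and 3 comparisons had none.

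Among the gene lists, perifosine alone shifted that of cholesterol synthesis and uptake most. All 14 measured members of the list of cholesterol synthesis and uptake had higher values with perifosine than in control cells, with a median log2 change of 0.64 (camera, adjusted p = 2.22e-23, and adjusted p = 0.0072 with an estimated correlation). The list mean was 0.69 ± 0.0404 log2 units above control (SD, n = 3), and it was above control within each letter. The members with the largest values, chosen after they were seen, were HMGCS1, which encodes a synthase of the mevalonate pathway, at 1.33 ± 0.298 (SE), the sterol oxidase gene MSMO1 at 1.27 ± 0.417, and LSS, which encodes lanosterol synthase, at 1.05 ± 0.175. None of these members passed the threshold over all genes, and 10 of the 14 passed when adjusted over the list alone.

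Other lists moved less with perifosine. The list of hypoxia and glycolysis fell, with a median of -0.11 and 14 of 17 members below control (adjusted p = 0.000482). This call was lost with an adjusted p = 0.07 with an estimated correlation. The targets of ATF4 and the integrated stress response were higher by a median of 0.15 in camera (adjusted p = 0.00462), with adjusted p = 0.677 with an estimated correlation. Fatty acid synthesis genes were higher by a median of 0.27 (adjusted p = 0.0237) and NRF2 targets by 0.13 (adjusted p = 0.0471), with adjusted p = 0.377 and adjusted p = 0.239 with an estimated correlation. No member of these 4 lists passed over all genes. TRIB3, a pseudokinase gene induced by ATF4 whose product binds AKT (Entrez Gene 57761), had a log2 change of 0.43 ± 0.276 (SE) and did not pass (adjusted p = 1).

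No gene passed the threshold for perifosine against control in limma. The unadjusted p was under 0.05 for 198 genes, fewer than the 405 that chance gives among 8092 tests, and the replicate block also gave 0 genes, with 326 at an unadjusted p under 0.05. With array weights 2 genes passed, both chosen after their values were seen. LSS was higher by 1.15 ± 0.145 (SE) and MYLIP, which encodes a ubiquitin ligase, was lower by a log2 change of -1.01 ± 0.138 (adjusted p = 0.0426 and 0.0432).

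Among the drug target kinases, AKT1, AKT2, ARAF, MAP2K1, MAP2K2, MAPK3 and MTOR were measured, and none passed in any of the 3 comparisons with control. The value of largest size was that of MAP2K1 with sorafenib, at -0.44 ± 0.177 (SE, adjusted p = 0.229). AKT2 was not above background on any control array. FLT3, FLT4, KDR, KIT, PDGFRB and RET, receptor targets of sorafenib or its relatives, were not above background on 3 arrays.

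Several lists that fit the drugs or the cell type did not pass against control in camera. Adjusted p-values are given here for perifosine, sorafenib and the combination in this order. The proapoptotic BCL2 family and death receptors had adjusted p = 0.355, 0.139 and 0.184, and antiapoptotic genes had adjusted p = 0.647, 0.302 and 0.534. FOXO targets, which AKT holds back, had adjusted p = 0.875, 0.815 and 0.971, with a positive mean (0.01) and median (0.03) only for the combination. NF-kB targets had adjusted p = 0.795, 0.678 and 0.389, and genes typical of Hodgkin and Reed-Sternberg cells had adjusted p = 0.632, 0.867 and 0.971. Autophagy and lysosome genes had adjusted p = 0.355, 0.638 and 0.843, interferon-stimulated genes adjusted p = 0.355, 0.148 and 0.123, and the drug target kinases adjusted p = 0.386, 0.56 and 0.759. MAPK pathway output had adjusted p = 0.474, 0.169 and 0.389, and for perifosine its median (-0.05) and its mean (0.11) differed in sign.

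**Figure D2:**
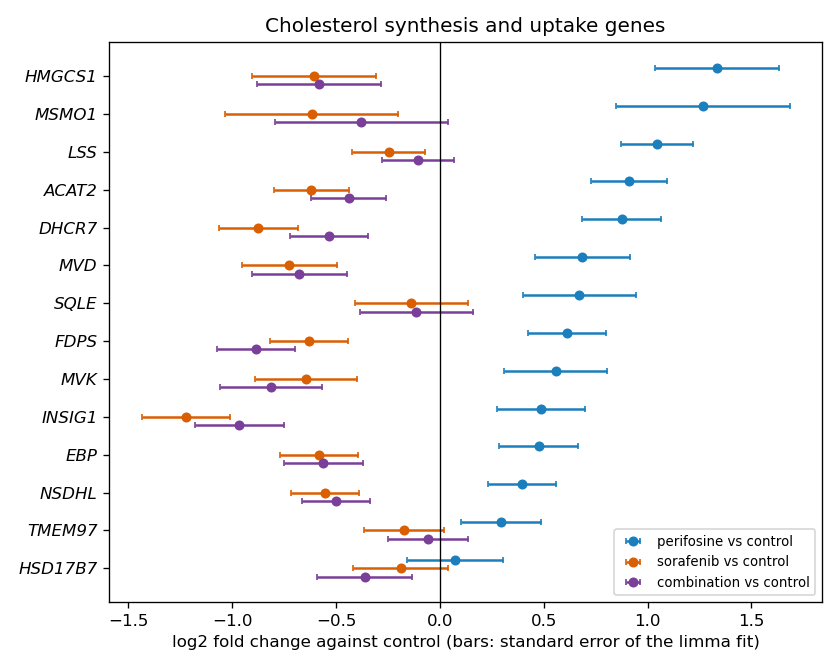
Log2 fold change against control (horizontal axis) of the 14 measured genes of the list of cholesterol synthesis and uptake, with points for perifosine, sorafenib and the combination and bars for the standard error of the limma fit. All 14 points for perifosine lie above 0, and all 14 for sorafenib and all 14 for the combination lie below 0.

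Sorafenib raised 78 genes and lowered 42. TRIB3 rose by 1.99 ± 0.276 log2 units, or 3.98-fold (SE, adjusted p = 0.00788), with a mean log2 intensity of 13.18 ± 0.34 (SD, n = 3). Other large rises were those of CSNK1G1, a casein kinase gene, by 2.07 ± 0.271, CDC14B, a phosphatase gene, by 1.87 ± 0.236, ALOX5AP, which encodes the activator of arachidonate 5-lipoxygenase, by 1.91 ± 0.227, and CCPG1, a receptor of autophagy in the endoplasmic reticulum, by 1.78 ± 0.217. CSNK1G1 and CDC14B each had 1 other kept probe, which was higher too but did not pass over all kept probes. SH3RF2 rose by 1.72 ± 0.36. LOC374443, detected on 1 of 3 control arrays, was at least 2.51-fold higher. ITGAL, the gene of an integrin of leukocytes, was not above background on any control array and was at least 2.05-fold higher with sorafenib (adjusted p = 0.00647).

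The largest fall with sorafenib was that of IL22, a cytokine gene, with a log2 change of -2.09 ± 0.286 (SE, adjusted p = 0.00788). HK2, which encodes a hexokinase of the first step of glycolysis, changed by -1.67 ± 0.158 (adjusted p = 0.0022), and the transporter gene SLCO4A1 by -1.41 ± 0.23. IL22 and HK2 each had 1 other kept probe, which was lower too but did not pass over all kept probes. ZNF395 changed by -1.39 ± 0.228, and PDE1B, a phosphodiesterase gene detected on 1 of 3 sorafenib arrays, was at least 2.04-fold lower. The histone gene H2AC8 was not above background on any sorafenib array and was at least 1.27-fold lower. HNRNPA1 had a log2 change of -1.37 ± 0.29, which is uncertain because its probe can bind near-identical copies of this gene.

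By list, sorafenib lowered hypoxia and glycolysis most firmly. 16 of 17 measured members had values below control, 5 fell over all genes and 11 adjusted over the list alone, and the median was -0.70 (camera, adjusted p = 2.14e-10, and adjusted p = 0.00692 with an estimated correlation). Among them, besides HK2, were PGK1 at -1.05 ± 0.154, PFKFB3, which makes an activator of phosphofructokinase, at -0.83 ± 0.151, and GPI at -0.81 ± 0.178. With the replicate block 9 members fell over all genes. The other 9 lists that passed in camera did not pass with an estimated correlation.

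ATF4 and integrated stress response targets rose with sorafenib, with 25 of 27 members above control and a median of 0.65 (adjusted p = 4.13e-13, and adjusted p = 0.0861 with an estimated correlation). Over all genes 3 members rose, namely TRIB3, PSAT1 of serine synthesis by 0.78 ± 0.171 and the glycyl-tRNA synthetase gene GARS1 by 0.67 ± 0.141. With the replicate block 10 rose and 1 fell over all genes. Adjusted over the list alone, 20 rose and 1 fell.

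Cholesterol genes fell with sorafenib, opposite to their direction with perifosine. All 14 members had values below control, with a median of -0.61 (adjusted p = 4.54e-07, and adjusted p = 0.0861 with an estimated correlation). Of these, INSIG1, whose product holds back the sterol-responsive transcription factors, fell by 1.22 on the log2 scale (SE 0.214, adjusted p = 0.0205), and DHCR7, of the last step of cholesterol synthesis, changed by -0.87 ± 0.189. Adjusted over the list alone, 8 fell.

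Targets of JAK-STAT signalling were lower, with a median of -0.65 (adjusted p = 0.000104, and adjusted p = 0.32 with an estimated correlation). CISH changed by -0.99 ± 0.199 and the kinase gene PIM2 by -0.76 ± 0.156, and with the replicate block 4 members fell in place of 2. DNA replication genes had a median of -0.26 (adjusted p = 1.55e-05, and adjusted p = 0.32 with an estimated correlation), with falls of the licensing factor gene CDT1 (-0.83 ± 0.134) and the thymidine kinase gene TK1 (-0.62 ± 0.135), and with the block 7 members fell in place of 2. Mitosis genes had a median of -0.24 with no member past the threshold and 3 lower with the block (adjusted p = 0.00179, and adjusted p = 0.0861 with an estimated correlation). The endoplasmic reticulum chaperones had a median of -0.33 (adjusted p = 0.0206), and MANF fell among them by 0.68 on the log2 scale. Heat shock proteins had a median of -0.22 (adjusted p = 0.0206). For both of these lists the adjusted p was 0.0861 with an estimated correlation. Ribosome biogenesis and MYC targets had a median of -0.30 (adjusted p = 0.0184, and adjusted p = 0.529 with an estimated correlation).

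In total, 120 of 8092 genes passed for sorafenib against control, 45 higher and 15 lower by at least 2-fold. With the letter as a replicate block 404 genes passed (227 higher and 177 lower), all 120 among them, and fatty acid synthesis genes passed as a list (adjusted p = 0.0478, against 0.0572 without the block, and adjusted p = 0.32 with an estimated correlation). The count fell to 8 with median scaling and to 72, 30 and 29 without control arrays A, B and C and to 42, 40 and 19 without sorafenib arrays A, B and C, and it rose to 263 without combination array B, an alternative chosen after seeing the data.

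**Figure D3:**
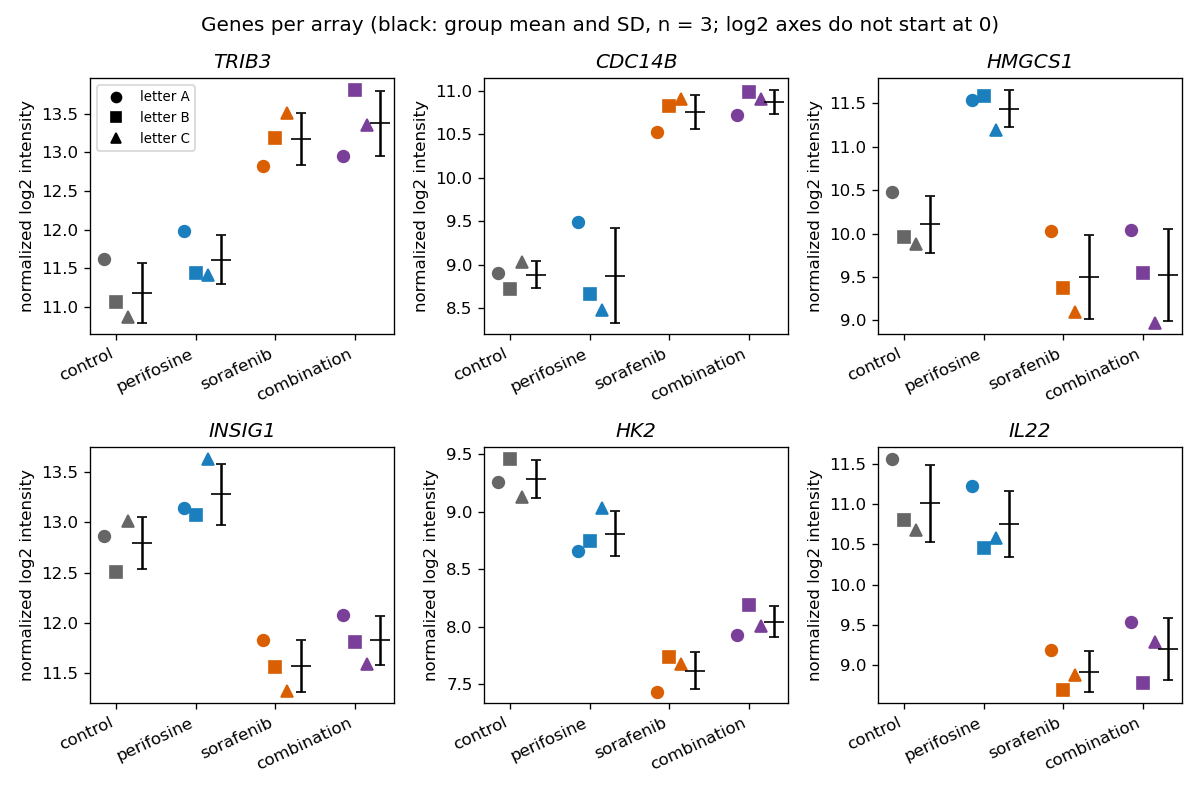
Normalized log2 intensity (vertical axis) of 6 genes on each of the 12 arrays, with a symbol per letter and, in black, the group mean and SD (n = 3). TRIB3 and CDC14B lie higher and INSIG1, HK2 and IL22 lower in the 6 arrays with sorafenib, and HMGCS1 lies highest in the 3 perifosine arrays.

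The combination of both drugs raised 187 genes and lowered 87 against control. CSNK1G1 rose by 2.28 ± 0.271 log2 units (SE), TRIB3 by 2.20 ± 0.276, CCPG1 by 2.05 ± 0.217, CDC14B by 1.98 ± 0.236 and SH3RF2 by 1.91 ± 0.36. RIPOR2 rose by 1.72 ± 0.274 and ALOX5AP by 1.65 ± 0.227, and ITGAL was at least 1.46-fold higher. The largest falls were those of the linker histone gene H1-2 (-2.27 ± 0.406, adjusted p = 0.0168), IL22 (-1.82 ± 0.286), the homeobox gene HLX (-1.80 ± 0.408) and ANKRD37 (-1.60 ± 0.378). For each of these genes array B was the lowest combination array, so their falls are larger with it than without it. H1-2 was at 7.62 on array B, against 9.22 and 8.66 on combination arrays A and C. SPINK6 was at least 2.2-fold lower, PDE1B at least 2.01-fold, ETNK1 at least 1.33-fold and H2AC8 at least 1.15-fold, since none was above background on a combination array.

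Stress response targets rose together with the combination. Of 27 members 26 were above control and 11 rose over all genes, or 23 adjusted over the list alone, with a median of 0.79 (camera, adjusted p = 9.57e-15, and adjusted p = 0.125 with an estimated correlation). They include DDIT3, a transcription factor gene of the stress response, by 1.39 ± 0.288, and PPP1R15A, a phosphatase subunit that reverses the phosphorylation of eIF2 alpha, by 1.28 ± 0.223. Hypoxia and glycolysis genes fell in 7 of 17 members over all genes and in 10 adjusted over the list alone, with a median of -0.59 (adjusted p = 1.57e-07, and adjusted p = 0.0207 with an estimated correlation). Among them, besides ANKRD37, were HK2 at -1.24 ± 0.158, PGK1 at -1.23 ± 0.154 and TPI1 at -0.82 ± 0.158.

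Cholesterol genes were below control in all 14 members with the combination, with a median of -0.52 (adjusted p = 2.07e-05, and adjusted p = 0.125 with an estimated correlation). INSIG1 changed by -0.97 ± 0.214 and FDPS, of the isoprenoid branch, by -0.88 ± 0.188, and 7 members fell adjusted over the list alone. JAK-STAT targets had a median of -0.75 (adjusted p = 0.000386, and adjusted p = 0.392 with an estimated correlation), with falls of CISH (-1.18 ± 0.199), PIM1 (-0.96 ± 0.228) and PIM2 (-0.86 ± 0.156). DNA replication genes had a median of -0.32 (adjusted p = 1.81e-05, and adjusted p = 0.358 with an estimated correlation), with falls of TK1 (-0.71 ± 0.135), CDT1 (-0.70 ± 0.134) and LIG1 (-0.58 ± 0.135).

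The endoplasmic reticulum chaperones had a median of -0.33 with the combination (adjusted p = 0.017), with falls of CALR (-0.93 ± 0.167) and MANF (-0.73 ± 0.147), and heat shock proteins one of -0.19 (adjusted p = 0.018). Both had an adjusted p of 0.125 with an estimated correlation. Mitosis genes had a median of -0.18 (adjusted p = 0.0149, and adjusted p = 0.16 with an estimated correlation). Ribosome biogenesis and MYC targets had a median of -0.30 (adjusted p = 0.0129, and adjusted p = 0.467 with an estimated correlation). The mitochondrial respiratory chain had a median of -0.37 with no member past the threshold (adjusted p = 0.000386, and adjusted p = 0.358 with an estimated correlation). Without combination array B, which was left out after seeing the data, its median was -0.17 (adjusted p = 0.0052).

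Over all genes 274 passed for the combination against control, 67 higher and 33 lower by at least 2-fold. The count fell to 153, 77 and 40 without control arrays A, B and C and to 183 and 107 without combination arrays B and C. With median scaling 4 genes passed, all of them higher (CSNK1G1, TRIB3, CCPG1 and CDC14B), against 68.2% higher among the 274. Whether the combination or sorafenib had more genes against control depended on the processing. Array weights gave 365 for the combination and 385 for sorafenib, and median scaling 4 and 8. Other alternatives kept the order, such as the replicate block (647 and 404). The larger count alone therefore does not show a broader response to the combination.

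The calls with sorafenib and with the combination overlapped. Of the 78 genes raised by sorafenib 73 were raised by the combination too, and of the 42 lowered 35 were, with 0 genes in opposite directions. Independent lists of these sizes would share 1.8 and 0.452 genes. Across genes, which are not independent replicates, the log2 changes of both comparisons had a correlation of 0.83 (Spearman 0.799), against 0.501 on average in 100 simulations of unchanged groups against the same controls with arrays drawn independently, and a covariance of 0.134 against 0.0327. The 3 control arrays could not be split, but the simulations share controls in the same way. The changes with perifosine share these control arrays too. Their covariance was 0.0273 with those of sorafenib and 0.0308 with those of the combination, against 0.0325 and 0.0326 simulated. The excess of 0.101 for sorafenib and the combination is what remains after the simulated covariance is subtracted. The simulated share of the control arrays is thus already taken out of it. The perifosine values are only a rough check of that share. Perifosine, sorafenib and control arrays were paired by letter, and the simulations hold no such pairing.

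**Figure D4:**
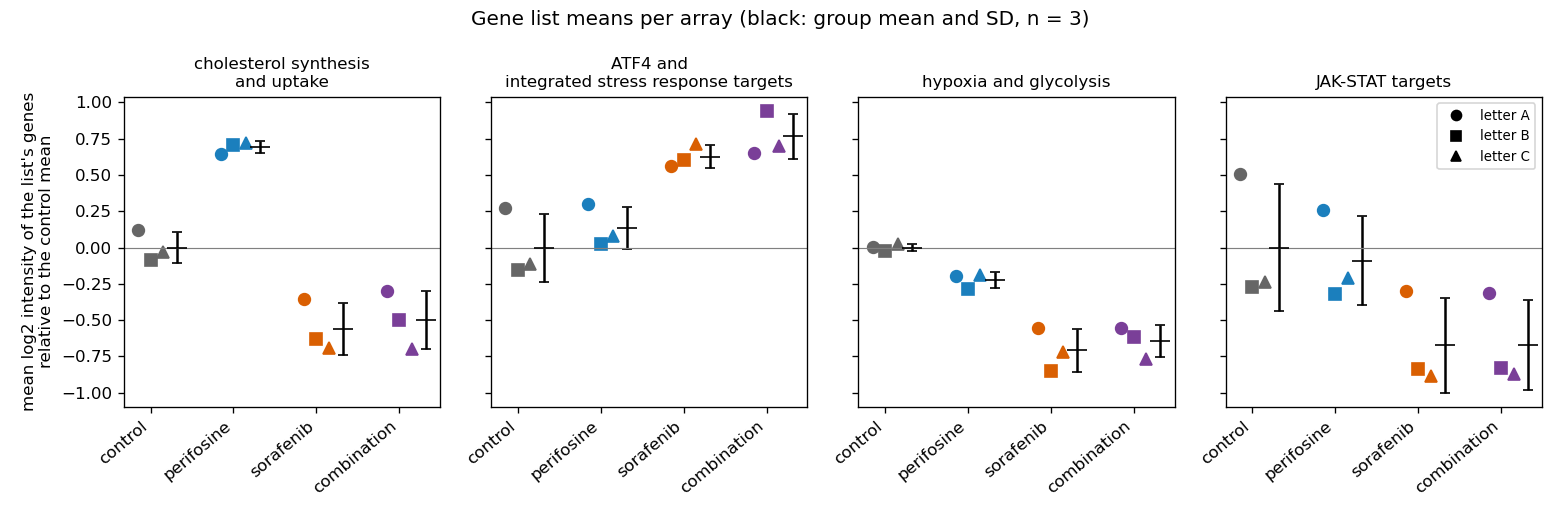
Mean log2 intensity of 4 gene lists relative to the control mean (vertical axis) on each of the 12 arrays, with a symbol per letter and, in black, the group mean and SD (n = 3). The cholesterol list lies at 0.69 ± 0.0404 with perifosine, at -0.56 ± 0.179 with sorafenib and at -0.50 ± 0.201 with the combination.

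Adding sorafenib to perifosine, as the combination against perifosine shows, lowered the cholesterol genes. Of 14 members 10 fell over all genes and 12 adjusted over the list alone, with a median of -1.36 (camera, adjusted p = 6.4e-17, and adjusted p = 0.0211 with an estimated correlation). HMGCS1 changed by -1.92 ± 0.298 log2 units (SE, adjusted p = 0.0111), FDPS by -1.50 ± 0.188, INSIG1 by -1.45 ± 0.214 and DHCR7 by -1.41 ± 0.189. Of the fatty acid genes SCD changed by -1.08 ± 0.181 and FASN by -0.98 ± 0.198, and that list had a median of -0.32 (adjusted p = 0.022, and adjusted p = 0.33 with an estimated correlation).

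The largest rises in the combination over perifosine were those of CDC14B (1.99 ± 0.236), TRIB3 (1.77 ± 0.276), SH3RF2 and CCPG1 (1.69 ± 0.36 and 1.69 ± 0.217). TPM3P9, a pseudogene whose probe can bind copies, was at least 2.6-fold higher and is uncertain. Large falls besides HMGCS1 were those of H1-2 (-1.85 ± 0.406), S100A13 (-1.57 ± 0.311) and IL22 (-1.56 ± 0.286). H1-2 and IL22 were lowest on combination array B. The chemokine gene CCL3, detected on 1 of 3 combination arrays, was at least 1.86-fold lower, and its probe can bind near-identical copies. Of the 2 other probes of S100A13, 1 had this sign. Stress response targets had a median of 0.60, with 6 rises over all genes, among them DDIT3 (1.41 ± 0.288), PPP1R15A (1.36 ± 0.223) and SARS1 (1.27 ± 0.254). The adjusted p of that list was 2.18e-11, and the adjusted p was 0.134 with an estimated correlation.

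TNFRSF10B, a receptor for the death ligand TRAIL, rose by 1.13 ± 0.259 in the combination over perifosine (adjusted p = 0.0447). It belongs to the list of proapoptotic genes (median 0.42, adjusted p = 0.042, and adjusted p = 0.176 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.33 with 5 falls (adjusted p = 8e-05, and adjusted p = 0.0506 with an estimated correlation), among them PFKFB3 (-0.87 ± 0.151) and PGK1 (-0.85 ± 0.154). CISH changed by -1.27 ± 0.199, CALR by -0.91 ± 0.167, TK1 by -0.67 ± 0.135 and CDT1 by -0.61 ± 0.134. Their lists and 3 more, namely heat shock proteins, ribosome biogenesis and the respiratory chain, were lower in camera (adjusted p from 0.000525 to 0.022), and none of these 6 passed with an estimated correlation (adjusted p from 0.122 to 0.552). Without combination array B, left out after seeing the data, the respiratory chain had a median of -0.12, against -0.26 with it.

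In total 193 genes passed for the combination against perifosine, 128 higher and 65 lower. The count fell to 30 and 30 without perifosine arrays B and C and to 84, 121 and 56 without combination arrays A, B and C. With median scaling 3 genes passed, all of them higher, namely CDC14B, TPM3P9 and KRTAP17-1, the last chosen after its values were seen, against 66.3% higher among the 193.

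Adding perifosine to sorafenib changed no gene past the threshold. In limma 0 genes passed for the combination against sorafenib, with 163 at an unadjusted p under 0.05 where chance gives 405. HMGCS1 was at 0.03 ± 0.298 (SE) and LSS at 0.14 ± 0.175, both chosen after their values were seen and both smaller than their error. The 95% interval of the log2 difference had a median half-width of 0.464, and it lay within 1 unit of 0 for 84.6% of the genes. By list, stress response targets were higher by a median of 0.14 (camera, adjusted p = 0.0429, and adjusted p = 0.826 with an estimated correlation), and with median scaling their median was -6.53e-05 (adjusted p = 0.278, in a range from 0.0108 to 0.909 over the alternatives). The respiratory chain was lower by a median of -0.27 (adjusted p = 0.0026, and adjusted p = 0.826 with an estimated correlation). Without combination array B, left out after seeing the data, neither list passed, with an adjusted p of 0.812 for each and medians of 0.01 and -0.03.

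Set directly against each other, the drugs differed most in the cholesterol genes. With perifosine 10 of 14 were higher than with sorafenib over all genes, and 13 adjusted over the list alone, with a median of 1.27 (camera, adjusted p = 1.62e-19, and adjusted p = 0.0132 with an estimated correlation). HMGCS1 was higher by 1.94 ± 0.298 log2 units (SE), DHCR7 by 1.75 ± 0.189, INSIG1 by 1.71 ± 0.214 and ACAT2 by 1.53 ± 0.181. The fatty acid genes FASN and SCD were higher by 1.29 ± 0.198 and 1.04 ± 0.181, and their list had a median of 0.30 (adjusted p = 0.00151, and adjusted p = 0.148 with an estimated correlation). Hypoxia and glycolysis genes were higher with perifosine by a median of 0.46 (adjusted p = 9.45e-07, and adjusted p = 0.0161 with an estimated correlation), with HK2 at 1.19 ± 0.158 and PFKFB3 at 0.92 ± 0.151.

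IL22 was higher with perifosine than with sorafenib by 1.83 ± 0.286, and CCL3 at least 2.06-fold. Lower with perifosine were CDC14B (-1.88 ± 0.236), ALOX5AP (-1.71 ± 0.227), the zinc finger gene ZFAND2A (-1.66 ± 0.231), ITGAL (at least 2.05-fold, detected on 1 of 3 perifosine arrays) and KRTAP17-1 (at least 2.34-fold). TRIB3 was lower by a log2 change of -1.57 ± 0.276, PPP1R15A by -1.09 ± 0.223 and CEBPG by -0.83 ± 0.168, and stress response targets had a median of -0.47 (adjusted p = 5.24e-09, and adjusted p = 0.148 with an estimated correlation). The death receptor gene FAS was at least 1.47-fold lower, and its list of proapoptotic genes had a median of -0.57 (adjusted p = 0.048, and adjusted p = 0.148 with an estimated correlation). FEN1 and CDT1 of DNA replication were higher by 1.04 ± 0.211 and 0.74 ± 0.134, and CISH by 1.08 ± 0.199. The DNA replication list had a median of 0.19 (adjusted p = 0.00139, and adjusted p = 0.43 with an estimated correlation). Mitosis genes had a median of 0.16 (adjusted p = 0.048, and adjusted p = 0.23 with an estimated correlation) and heat shock proteins one of 0.18 (adjusted p = 0.0135, and adjusted p = 0.107 with an estimated correlation). Ribosome biogenesis and MYC targets had a median of 0.22 (adjusted p = 0.0421, and adjusted p = 0.6 with an estimated correlation). Higher with perifosine in camera were also the lists of MAPK pathway output (median 0.36, adjusted p = 0.048, and adjusted p = 0.148 with an estimated correlation) and JAK-STAT targets (median 0.52, adjusted p = 0.00151, and adjusted p = 0.428 with an estimated correlation).

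Over all genes 83 passed for perifosine against sorafenib, 34 higher and 49 lower with perifosine. With the replicate block the members past the threshold went from 2 to 6 for DNA replication, from 1 to 4 for JAK-STAT targets, from 2 to 5 for hypoxia and glycolysis, from 0 to 2 for MAPK pathway output, and for stress response targets from 3 lower to 5 lower and 1 higher. The block gave 368 genes (170 higher and 198 lower), all 83 among them, and with it the chaperone list no longer passed (adjusted p = 0.0584, against 0.0384, and adjusted p = 0.148 with an estimated correlation). The count fell to 19 and 23 without perifosine arrays B and C and to 31, 48 and 19 without sorafenib arrays A, B and C, and rose to 214 without combination array B, left out after seeing the data.

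The interaction asks whether the combination departed from the sum of the separate changes. The cholesterol list lay below that sum in all 14 members, with a median of -0.64 (camera, adjusted p = 2.15e-12, adjusted p = 0.0555 with an estimated correlation, and fry adjusted p = 0.103). Among its members, chosen after their values were seen, HMGCS1 was at -1.31 ± 0.422 (SE) and LSS at -0.90 ± 0.247. Hypoxia and glycolysis genes lay above the sum in 16 of 17 members, with a median of 0.20 (adjusted p = 0.00213, and adjusted p = 0.112 with an estimated correlation). No single gene passed in limma, with 163 at an unadjusted p under 0.05, and in simulations of this size 3.22% of 2-fold departures were recovered.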

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

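The test chosen only after the result was seen is the direct comparison of perifosine with sorafenib for the cholesterol genes. The effect of perifosine differed with and without sorafenib for 2 gene lists, each by a test of the interaction itself. The list of cholesterol synthesis and uptake had a median interaction of -0.643 (camera, adjusted p = 2.15e-12), and the list of hypoxia and glycolysis one of 0.205 (adjusted p = 0.00213). With an estimated correlation neither passed (adjusted p = 0.0555 and 0.112), and with fry neither did (adjusted p = 0.103 and 0.167). The rule for a sample far from the others needs at least 4 samples per group and was not applied to groups of 3.

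For the cholesterol genes, higher with perifosine alone and lower with sorafenib with or without perifosine, the direct comparison of perifosine with sorafenib, which uses no control array, gave a median difference of 1.27. It follows from the values against control, so it argues against chance values of the shared control arrays only for the difference between the drugs, and the direction of each drug rests on the 3 control arrays (SD of the list mean 0.107). Differences between the replicate letters are argued against by the list means within letters, where perifosine lay above control by 0.526 at least and sorafenib below it in each of the 3 letters. The normalization is argued against by 4 other corrections and scalings, with medians of at least 0.411 for perifosine and at most -0.292 for sorafenib. Among these, no background correction and the authors' normalized values gave nearly the same medians (-0.294 and -0.292 for sorafenib), so they hardly count as separate checks. A candidate explanation is that the cells sensed opposite changes in sterol supply, tested with the liver X receptor targets apart from MYLIP, for which camera gave a p of 0.76 in perifosine against sorafenib. Only LPCAT3 (0.45) and SMPDL3A (-0.77) of these targets were measured, which is too few to count the result against it, although the prediction written before would have done so. MYLIP itself was lower with perifosine than with sorafenib, by a log2 change of -1.64 ± 0.151 (SE, limma, adjusted p = 0.00163). That value had been seen before the explanation was written, so it is no test of it, and the explanation stays open.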

How the results depend on the processing

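The tests chosen after seeing the data are those with the block without combination array B or without all combination arrays, those without combination array B in comparisons that do not hold the combination, and the values of the gene lists with an array left out. No gene or list past the threshold turned its direction in its test. For perifosine the lists of NF-kB targets and of T and NK cell markers, which did not pass, had the other direction in camera with the block. The median of the stress response list in the combination against sorafenib was -6.53e-05 with median scaling, where it no longer passed. No scaling moved the median of all genes by over 0.1. The causes of the changes in counts below were not tested; the alternatives that leave out arrays use fewer arrays by construction, and no detection filter tests more genes. For perifosine against control array weights gave 2 genes, and the other alternatives 0. For sorafenib against control (120) no background correction gave 292, normexp without control probes 205, median scaling 8, the authors' normalized values 292, no detection filter 35, detection on all 12 arrays 235, the replicate block 404, only the groups compared 13, eBayes with trend and robust 239, array weights 385, and the block without combination array B 800 or without all combination arrays 618. For the combination against control (274) the values outside 1.5 times were 547 without background correction, 4 with median scaling, 544 with the authors' values, 78 without the filter, 428 with detection on all arrays, 647 with the block, 16 with only the groups compared, 483 with trend and robust, and 571 with the block without combination array B. For the combination against perifosine (193) they were 410 without background correction, 307 with normexp, 3 with median scaling, 409 with the authors' values, 53 without the filter, 323 with detection on all arrays, 494 with the block, 0 with only the groups compared, 360 with trend and robust, 368 with array weights, and 429 with the block without array B. For perifosine against sorafenib (83) they were 214 without background correction, 137 with normexp, 10 with median scaling, 215 with the authors' values, 33 without the filter, 163 with detection on all arrays, 368 with the block, 1 (MYLIP) with only the groups compared, 203 with trend and robust, 413 with array weights, 716 with the block without array B and 543 without all combination arrays. The genes shared by the calls with sorafenib and the combination (108) were 244 without background correction, 167 with normexp, 4 with median scaling, 245 with the authors' values, 31 without the filter, 183 with detection on all arrays and 319 with the block. Leaving out 1 array gave 19 to 263 genes for sorafenib against control, 40 to 202 for the combination against control, 30 to 171 for the combination against perifosine, 19 to 214 for perifosine against sorafenib, and 0 for the other 3 comparisons.

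Of the gene lists, an estimated correlation left 1 for perifosine (of 5), 1 for sorafenib (of 10), 1 for the combination (of 11), 1 for the combination against perifosine (of 12), 2 for perifosine against sorafenib (of 13) and 0 for the combination against sorafenib and for the interaction (of 2 each). With fry 1, 7, 0 and 0 passed for perifosine, the combination, the combination against sorafenib and the interaction. Without the detection filter 2 passed for perifosine and 1 for the combination against sorafenib, where detection on all arrays and the block each left 1, and leaving out combination array B left 0. Without that array 4 passed for perifosine, 12 for sorafenib, 12 for the combination, 12 for the combination against perifosine, 12 for perifosine against sorafenib and 2 for the interaction. The cholesterol list, with medians of -0.612, -0.517 and -0.643 for sorafenib, the combination and the interaction, which these tests cannot move, lost its call with an estimated correlation (adjusted p = 0.0861, 0.125 and 0.0555), and the interaction lost it with fry (adjusted p = 0.103). Leaving out 1 array, its median ran from 0.568 to 0.698 for perifosine, from -0.692 to -0.477 for sorafenib, from -0.65 to -0.374 for the combination and from -0.752 to -0.436 for the interaction. Of values for named genes past the threshold, 1474 stayed past it in the same direction and 542 did not, and for the lists 412 and 98. Of values for named genes not past it, 31 changed sign without passing and 387 kept their sign. Signal over background limits dim probes. On combination array B the median signal of the kept probes was 2.17 times that of probes with a high detection p on that array. On sorafenib array B it was 3.163 times. These are the arrays with the fewest and the most detected probes. A block for the slide was not run.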

Other observations

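The tests chosen only after the result was seen are the histone gene values and the fit with the letter as a block without the combination arrays. The set held the 24 measured histone genes whose symbols start with H1-, H2AC, H2BC, H3C or H4C. Histone genes with other symbols were left out. Most of the 24 did not pass the threshold in any comparison with control. As a set, chosen after H1-2 and H2AC8 had been seen, they were not tested. Of these 24 genes, 22 had negative log2 changes with sorafenib, 24 with the combination and 19 with perifosine, with medians of -0.70, -0.80 and -0.24. Past the threshold were 1 gene with sorafenib (H2AC8) and 3 with the combination (H1-2, H2AC8 and H2BC11, the last at -0.78), and 0 genes with perifosine in limma. Perifosine against sorafenib had a median of 0.46 for these genes. No explanation was tested for them.

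For perifosine alone fewer genes than chance gives had an unadjusted p under 0.05, namely 198 against 405. Too few arrays is argued against only where 200 genes change 2-fold, as simulated, of which 64.3% were recovered. Of 1.41-fold changes 0.025% were recovered. Smaller sets of changed genes were not simulated, so for these the simulations cannot decide. In the data HMGCS1 at 1.33 ± 0.298 (SE, limma adjusted p = 0.836) and MYLIP at -0.98 ± 0.151 (adjusted p = 0.194), both chosen after their values were seen, did not pass. Differences between the letters and the variable combination arrays may widen the shared spread: with the letter as a block and without the combination arrays, 467 genes had an unadjusted p under 0.05, against 394 by chance, and 0 passed after adjustment. No biological explanation was tested.

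Combination array B lay apart from the other combination arrays. Lower signal over background on that array is argued against as the whole cause by its bright genes, whose SD of the difference from the other combination arrays was 0.516 in the brightest class, against 0.292 at most on the 9 arrays of the other groups. Combination arrays A and C, at 0.356 and 0.337, lay above that range too, but each was measured against a mean that includes array B. RNA of cells without sorafenib under a wrong label is argued against by the genes called with sorafenib, over which the mean shift of this array was 96% of that of the sorafenib arrays. What set the array apart stays open, and no biological explanation was tested.

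The 6 arrays of each comparison of groups can be split into equal groups in 10 ways, which is too few for a share under 0.05. The real split gave 120 genes for sorafenib against control, 274 for the combination against control, 193 for the combination against perifosine and 83 for perifosine against sorafenib, and the highest other split gave 0 genes in each, so that 1 split of 10 reached the real count. For perifosine against control and for the combination against sorafenib the real count and the highest other count were 0, so all 10 splits reached it. For the interaction the real count was 0, the highest of the other random orders gave 3, and 100 of 100 random orders reached the real count, as any order must for a count of 0.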
